A study of Cucumis melo with 62 samples.

How the data were processed

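RNA was measured by sequencing in 62 libraries of melon (Cucumis melo) fruit harvested at about 45 days after flowering, per the labels' protocols. The deposited values lie in 2 tables. The first holds 38 libraries of the cultivars F39 and TTDV from 7 environments: Georgia, North Carolina, Uvalde, Arizona and California in 2019, Uvalde in 2018 and, for TTDV alone, Indiana in 2019. The second holds 24 libraries of 8 cultivars grown at Weslaco, Texas, in 2019. Per the labels' protocols, RNA was extracted from frozen powdered tissue with Trizol on a column and treated with DNase, and libraries were made with an mRNA kit (Universal Plus mRNA-seq).

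Both deposited tables hold variance-stabilised values on a log2-like scale for 29980 gene IDs, 1 column per library, and the submitters' processing notes name DESeq and DESeq2 with no version. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The lowest value in both tables was 4.182278, the value of a count of 0. Inverting the variance-stabilising formula gave whole reads in every library, with at least 99.9555% of the values within 0.05 of a whole number, and so returned each library's total and size factor. The transform compresses low counts. A doubling from 10 normalised reads moves the value by 0.405, from 100 reads by 0.812 and from 1000 reads by 0.975, so differences of weakly read genes are understated against a fold change. Values in the text called reads are these recovered reads divided by the size factor. A count of 0 allows up to 3 reads, and such limits cover counting error only.

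Totals ranged from 4041908 recovered reads (CRUSER replicate 1) to 31333150 (F39 North Carolina replicate 1), with a median of 16376816. The 10 most abundant genes took between 4.54% and 22.7% of a library's reads, so the totals alone do not set the precision of weakly read genes. Between 16004 and 20986 genes had a read per library.

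Libraries were grouped by cultivar, location and year as the labels give them, in 13 groups of the first table and 8 of the second. Each group had 3 libraries except TTDV Georgia, which had 2. The labels give no batch, and do not say whether libraries of a group came from separate plants or fields, so p-values measure only the spread between these samples. The columns carry no replicate number, and the replicate numbers used here only name libraries. The Indiana libraries are labelled with Texas in brackets, while the protocol lists Indiana as a field. They are called Indiana here.

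Genes were tested where at least 3 libraries of the table lay at least 1 unit above the lowest value (about 9.08 normalised reads), which kept 17383 and 17131 genes. The main test was limma 3.58.1 in R 4.3.3 with 1 coefficient per group over all libraries of the table, and empirical Bayes moderation with a trend and robust settings. Benjamini-Hochberg adjusted p under 0.05 was the threshold, applied to each comparison separately. Differences and their standard errors (SE) are on the deposited log2-like scale. In limma the tables were tested apart and never against each other. Only the read levels of some genes and the gene loadings of the principal components were set side by side across the tables. The comparisons, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

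The rule for named genes took, for each comparison, the genes past the threshold with the largest differences that met a further condition. At Weslaco and for Indiana, the libraries compared did not overlap. For the mean cultivar difference, the group means differed in the same direction in each environment. For the other locations and the year, the difference had the same direction in each cultivar. A gene named for a location could therefore overlap with single other locations. As no table paired the gene IDs with product names, the rule allowed at most 2 IDs that rose and 2 that fell per comparison. The reference gene table (assembly USDA_Cmelo_AY_1.0) matched 0 of the IDs. None of the 20 gene lists fixed beforehand was therefore tested, no product name is given, and no coordinates are printed.

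The alternatives were no filter and a stricter filter on low values (3 units, about 111 normalised reads), quantile normalization, moderation without trend and robust settings, sample weights, a fit over the compared groups only, and leaving out each library in turn. Chosen after the data were seen were limma's voom on the recovered reads, a fit without the 6 Uvalde 2019 libraries, a fit without a pair of libraries of different groups that resembled each other, and a fit without 2 F39 Georgia libraries. The difference between cultivars in each location's effect was also fitted without Uvalde 2019, again after the data were seen. The sample weights were planned with the default method of limma. It stopped before converging on the first table and gave TTDV North Carolina replicate 2 a weight of 6.01e-08, so the gene-by-gene method was used for both tables, a choice made after the counts from both methods were seen.

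The tests were checked on data simulated from the real libraries' means and depths, with 50 genes changed at each fold size. The changed genes were drawn only from genes with more reads than the filter asks for. All other genes had the same mean in every group, so recovery in the real data may be lower. For the mean cultivar difference, 44.0% of the 1.5-fold, 66.0% of the 2-fold and 90.0% of the 4-fold changes were recovered. For the cultivar difference at Arizona alone, 24.0% of the 2-fold and 58.0% of the 4-fold changes were recovered. The Indiana comparison recovered 16.0% of the 2-fold and 68.0% of the 4-fold changes.

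To score cultivar identity, marker genes were taken from the 4 environments Arizona, California, North Carolina and Uvalde 2018, as genes whose F39 and TTDV libraries were apart by at least 0.5 units with means differing by over 1.5 units. A library of one of these environments was scored with markers from the remaining ones. Further calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Other splits of the samples were drawn 100 times, or all 10 were run for 3 libraries against 3.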

Results

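Transcript levels were measured in fruit of 10 melon cultivars, harvested at about 45 days after flowering, to compare fruit grown in different places and fruit of different cultivars. The cultivars F39 and TTDV were grown in 6 shared environments, with TTDV also in Indiana, and 8 further cultivars (TH-5, TH-6, PRIMO, OC164, CRUSER, HD150, HD252 and Infinite Gold) were grown at Weslaco. The 38 libraries of F39 and TTDV held 6251302 to 31333150 reads, and the 24 Weslaco libraries held 4041908 to 21290476. Libraries of a group correlated across genes with r from 0.853 to 0.993 in the first table (median 0.967, 37 pairs) and from 0.915 to 0.984 in the second (median 0.952, 24 pairs). No pair of a group came near counting noise, as the median squared difference per gene was at least 5.49 times its Poisson value. Of the 38 libraries, 29 were most similar to a library of their own group, as were 18 of the 24 at Weslaco. Gene IDs are given as deposited, since no product names were matched to them.

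**Figure D1:**
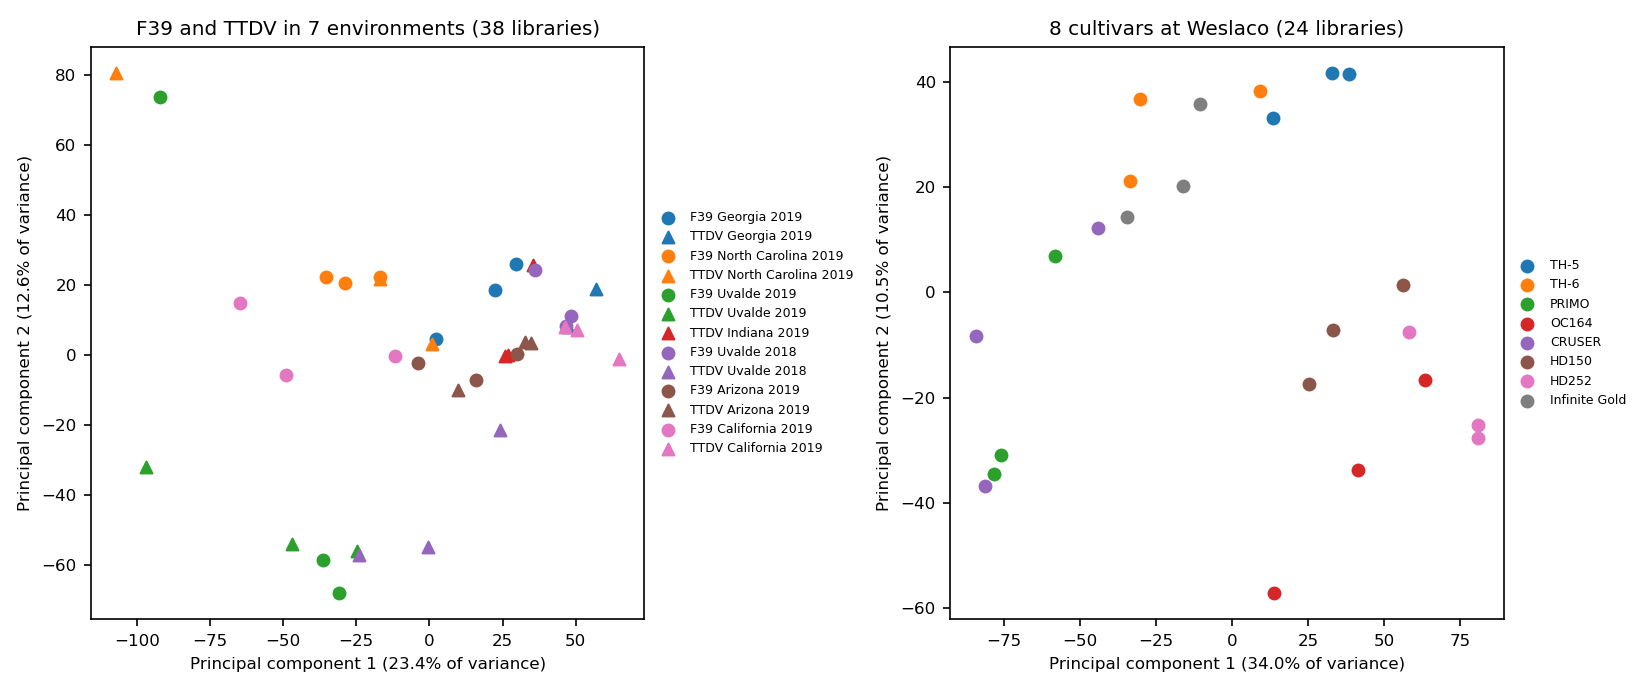
Each point is a library placed by principal components 1 and 2 of the filtered log2-like values, with F39 and TTDV in 7 environments on the left (circles F39, triangles TTDV) and the 8 Weslaco cultivars on the right. The first components hold 23.4% and 34% of the variance, and on the left TTDV North Carolina replicate 3 and F39 Uvalde 2019 replicate 3 lie together at the upper left, apart from their groups.

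Whether the labels of F39 and TTDV separate the libraries was examined first. MELO3C016167.2 had 20035 ± 3557 reads (SD, n = 3) in F39 and 256 ± 302 (n = 3) in TTDV at Arizona, and 24473 ± 5075 and 122 ± 98.9 at Uvalde 2018 (n = 3 each). At Uvalde 2019 the libraries labelled F39 had 702 ± 299 reads and those labelled TTDV had 15533 ± 7033 (n = 3 each). MELO3C024745.2 had 6.57 ± 0.72 reads in F39 and 2128 ± 830 in TTDV at Arizona, but 797 ± 126 in the libraries labelled F39 and 2.65 ± 2.48 in those labelled TTDV at Uvalde 2019 (n = 3 each). With 43 marker genes chosen in 4 other environments (29 high in TTDV and 14 high in F39), 6 of the 6 Uvalde 2019 libraries lay on the side of the other cultivar. F39 Georgia replicates 2 and 3 each had 34.9% of these markers on the TTDV side, against 0.0% in replicate 1. Of the libraries outside Uvalde 2019, 32 of 32 lay on the side of their own cultivar by the median score, those of Georgia and Indiana with the same 43 markers and the others with sets chosen without their own environment (65 markers for North Carolina, 55 for Uvalde 2018, 56 for Arizona and 57 for California). The labels were kept in every comparison, and each direction that draws on Uvalde 2019 is that of the libraries as labelled.

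**Figure D2:**
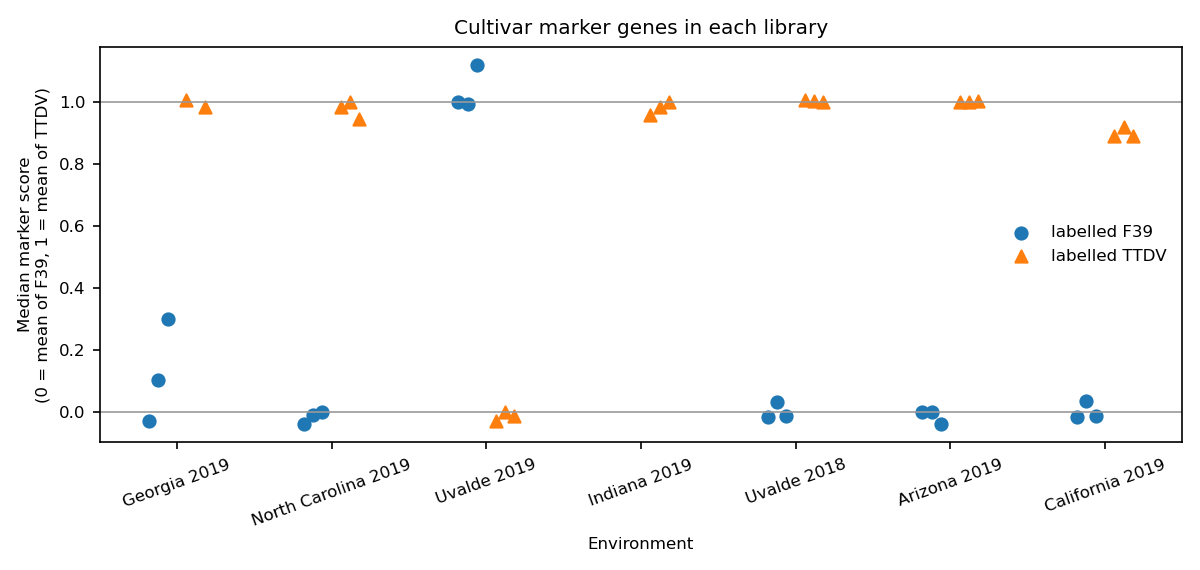
Each point is a library of F39 (circles) or TTDV (triangles) as labelled, placed by environment, with the median score of the cultivar marker genes on the vertical axis, where 0 is the mean of F39 and 1 the mean of TTDV in the environments used to choose the markers. The 6 Uvalde 2019 libraries lie at the level of the other cultivar, from -0.029 to 1.12, and F39 Georgia replicates 2 and 3 lie at 0.103 and 0.299.

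Averaged over the 6 shared environments, MELO3C010751.2 was higher in TTDV, at 448 ± 300 reads (SD, n = 17) against 47.9 ± 32.9 in F39 (n = 18), a difference of 2.26 ± 0.28 (SE) with adjusted p = 2.84e-06 in limma. MELO3C026184.2 was higher by 2.12 ± 0.32 (adjusted p = 3.49e-05), at 1090 ± 1172 against 199 ± 239 reads. MELO3C023484.2 was lower in TTDV, at 28.2 ± 29.3 against 223 ± 194 reads, a difference of -1.92 ± 0.27 (adjusted p = 1.92e-05), and MELO3C017305.2 differed by -1.92 ± 0.43 (adjusted p = 0.00402). The rule required these 4 genes to have the same direction in each of the 6 environments, the Uvalde 2019 libraries as labelled included, so this is not a result. If the cultivar labels at Uvalde 2019 were exchanged, these genes would run the other way there. In all, 1621 of 17383 genes passed the threshold, 909 higher and 712 lower in TTDV (56.1% higher, and 49.2% after quantile normalization, so the balance depends on the scaling). Without the 6 Uvalde 2019 libraries, a choice made after the data were seen, 3642 of 16850 genes passed, 1938 higher and 1704 lower. Chosen likewise, the fit without TTDV North Carolina replicate 3 and F39 Uvalde 2019 replicate 3 gave 2454, and gene-by-gene sample weights (used for every such count) gave 4536.

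In that comparison without Uvalde 2019, the same rule named 4 other genes. MELO3C024745.2 was higher in TTDV, at 1509 ± 680 reads (SD, n = 14) against 72.6 ± 180 in F39 (n = 15), a difference of 5.12 ± 0.34 (SE, limma adjusted p = 6.17e-11). The F39 mean was carried by Georgia replicates 2 and 3 (506 and 526 reads), with 0.76 in Georgia replicate 1 and up to 10.7 in the F39 libraries of the other 4 environments. MELO3C019745.2 differed by 4.29 ± 0.75 (adjusted p = 0.000176), with a spread in F39 from 1.57 to 28107 reads. Its highest F39 values were in Georgia replicates 2 and 3 (3779 and 28107 reads, against 3.8 in replicate 1 and 2782 and 4144 in TTDV there), so that the mean reads at Georgia were higher in F39. MELO3C016167.2 differed by -7.22 ± 0.26 (adjusted p = 1.9e-16), at 165 ± 205 reads in TTDV against 20854 ± 6681 in F39, and MELO3C018372.2 by -3.54 ± 0.35 (adjusted p = 4.89e-08), at 59.4 ± 49.9 against 1223 ± 786 reads. At Uvalde 2019 as labelled, the mean reads of all 4 genes ran the other way. Genes past the threshold with a difference of at least 1 unit in the remaining environments had the same sign in 88.2% of cases at Georgia, 81.5% at California, 77.5% at North Carolina, 72% at Arizona and 59.9% at Uvalde 2018. At Uvalde 2019 the share was 12.2% (82 of 671 genes).

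Within single environments the cultivar difference varied in extent. At Uvalde 2018, 3729 genes passed the threshold in limma (1862 higher and 1867 lower in TTDV), and at California 2920 did (1684 higher and 1236 lower). Fewer passed at Uvalde 2019 as labelled (830; 411 higher and 419 lower), North Carolina (707; 401 and 306), Georgia (393; 245 and 148) and Arizona (222; 132 and 90). The interaction test of the difference between environments passed for 5102 genes, and for 4397 without Uvalde 2019. At North Carolina the higher share was 56.7% in the main test and 47.7% after quantile normalization. With voom on recovered reads 74.5% of the Georgia genes were higher, against 62.3% in the main test, and 434 genes passed at Uvalde 2019. A fit over the compared groups only gave 7 genes at Georgia, 93 at North Carolina, 49 at Uvalde 2019, 703 at Arizona and 4444 at California, and the stricter filter gave 145 at Arizona. Without Uvalde 2019 the count at North Carolina was 1162. Sample weights gave 811 at Georgia, 4069 at North Carolina, 1655 at Uvalde 2019, 5684 at Uvalde 2018, 3773 at Arizona, 8209 at California and 11677 for the interaction.

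Single libraries moved several of these counts by over 1.5 times. At Georgia the count was 251 without TTDV replicate 1 and 38 without TTDV replicate 2, where the lone remaining TTDV library is assumed to vary like the other groups. At North Carolina it was 219 and 326 without F39 replicates 1 and 3, and 1499 and 338 without TTDV replicates 1 and 3. It was 2466 at Uvalde 2018 without TTDV replicate 3. At Arizona it was 142, 134 and 107 without F39 replicates 1, 2 and 3, and 96 and 92 without TTDV replicates 2 and 3. At California it was 1634 and 1724 without F39 replicates 1 and 2, and 1681 without TTDV replicate 3.

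Fruit transcript levels differed between environments within each cultivar. In F39, 6567 of 17383 genes differed over the 6 environments, and in TTDV 5519 differed over 7. Of these, 3033 were shared, against 2085.0 for independent lists. Both tests use the same estimate of each gene's spread, so genes with a low spread pass both more easily. The excess therefore does not show a shared response. Without the Uvalde 2019 libraries, 6334 genes differed in F39 and 4168 in TTDV, and with sample weights 12261 and 12830.

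At Georgia, MELO3C021688.2 had 140589 ± 198129 reads (SD, n = 5) against 16543 ± 26307 at the other 4 locations of 2019 (n = 24), a difference of 3.79 ± 0.74 (SE, limma adjusted p = 0.0037). MELO3C010779.2 was higher by 3.49 ± 0.69 (adjusted p = 0.00384), at 2462 ± 2347 against 345 ± 491 reads. MELO3C023255.2 differed by -2.98 ± 0.69 (adjusted p = 0.00905) and MELO3C016712.2 by -2.91 ± 0.73 (adjusted p = 0.0145). In all 1611 genes passed the threshold, 880 higher and 731 lower, with 54.6% higher in the main test and 65.6% with voom. The count was 612 without F39 Georgia replicate 3, 735 without F39 Georgia replicates 2 and 3, 853 without TTDV Georgia replicate 1, 678 without the Uvalde 2019 libraries and 25 without TTDV Georgia replicate 2. It was 2586 without TTDV North Carolina replicate 3 and F39 Uvalde 2019 replicate 3 and 2651 with sample weights. All 4 genes missed the threshold without TTDV Georgia replicate 2 (highest adjusted p = 0.147), and MELO3C023255.2 and MELO3C016712.2 also without TTDV Georgia replicate 1 (adjusted p = 0.0517 and 0.0577) and without F39 Georgia replicates 2 and 3 (adjusted p = 0.0534 and 0.0523). MELO3C023255.2 missed it without the Uvalde 2019 libraries as well (adjusted p = 0.0612).

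At North Carolina, MELO3C022772.2 had 35648 ± 20227 reads (SD, n = 6) against 4398 ± 11991 at the other locations (n = 23), a difference of 4.52 ± 0.68 (SE, limma adjusted p = 5.37e-05). MELO3C024582.2 differed by -3.82 ± 0.68 (adjusted p = 0.00031) and MELO3C014433.2 by -3.78 ± 0.66 (adjusted p = 0.000224), at 68.4 ± 67.2 against 2965 ± 6230 reads. MELO3C016562.2 was higher by 3.09 ± 0.93 (adjusted p = 0.0194). It missed the threshold without F39 North Carolina replicate 3 (adjusted p = 0.0593) and without TTDV North Carolina replicate 3 (difference 1.83, adjusted p = 0.15), within a range of 0.00234 to 0.15 over the libraries left out in turn. In all 3408 genes passed, 1611 higher and 1797 lower (47.3% higher, and 51.8% after quantile normalization), and sample weights gave 7806.

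At Uvalde 2019, where both cultivars enter with equal weight, MELO3C009034.2 had 30288 ± 21630 reads (SD, n = 6) against 8.81 ± 22.5 at the other locations (n = 23), a difference of 8.93 ± 0.69 (SE, limma adjusted p = 4.18e-10). MELO3C015419.2 had 64876 ± 76384 against 47 ± 154 reads, a difference of 8.85 ± 1.00 (adjusted p = 3.71e-07). MELO3C021688.2 differed by -4.56 ± 0.68 (adjusted p = 2.51e-05) and MELO3C010779.2 by -3.23 ± 0.63 (adjusted p = 0.00066), and both of these IDs were among those higher at Georgia. Each location enters the mean that the others are set against, so the Georgia and Uvalde 2019 differences are not independent. In all 3536 genes passed, 2099 higher and 1437 lower. The higher share was 59.4% in the main test and 46.3% after quantile normalization, so the balance of directions depends on the scaling. Sample weights gave 6498 genes. Reads of the first pair of genes overlapped with the other locations, with a lowest Uvalde 2019 library at 65.1 against a highest of 96.4 at the other 4 locations for MELO3C009034.2, and 114 against 714 for MELO3C015419.2. The 664 genes higher by at least 1 unit had a median of 146 to 189 reads in 5 of the 6 Uvalde 2019 libraries, 31.2 in F39 replicate 3 there, and 3.16 to 35.2 in the libraries from outside Texas, where TTDV North Carolina replicate 3 was the highest. A gap between Uvalde 2019 and the other 4 locations compared follows from this choice of genes.

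**Figure D3:**
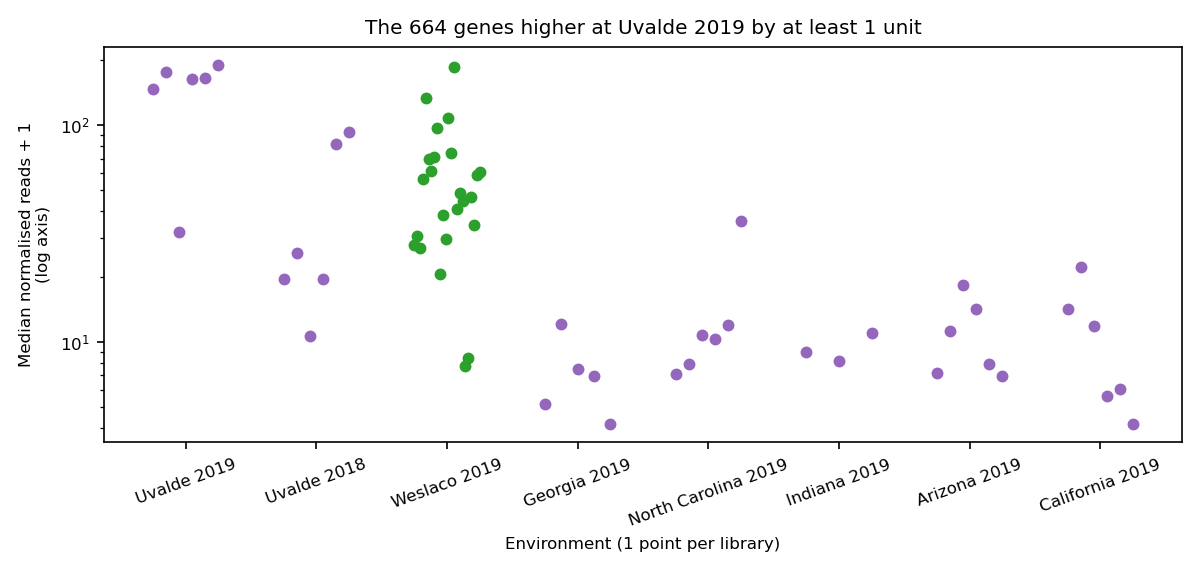
Each point is a library placed by environment, with the median normalised reads plus 1 over the 664 genes higher at Uvalde 2019 on a log axis. The Uvalde 2019 libraries reach 189 reads, with F39 replicate 3 apart at 31.2. Those of Uvalde 2018 run from 9.58 to 92.1 and those of Weslaco (green, the others purple) from 6.7 to 185. Both deposited tables share the lowest value 4.182278, which points to 1 transformation of both.

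At Arizona, MELO3C025025.2 had 186930 ± 120299 reads (SD, n = 6) against 58773 ± 100455 at the other 4 shared locations of 2019 (n = 23), a difference of 3.02 ± 0.52 (SE, limma adjusted p = 0.00132), and MELO3C024582.2 was higher by 2.76 ± 0.68 (adjusted p = 0.018). MELO3C022772.2, higher at North Carolina, differed here by -3.21 ± 0.68 (adjusted p = 0.00587), and MELO3C031322.2 by -2.96 ± 0.81 (adjusted p = 0.0319). North Carolina is part of the mean that Arizona is set against, and the reverse, so the differences at these locations are not independent. In all 838 genes passed, 523 higher and 315 lower. The count was 387, 379 and 472 without F39 Arizona replicates 1, 2 and 3, and 488, 295 and 351 without TTDV Arizona replicates 1, 2 and 3. It was 1445 without the Uvalde 2019 libraries, where MELO3C031322.2 differed by -1.17 (adjusted p = 0.29) in place of -2.96. The count was 1518 without TTDV North Carolina replicate 3 and F39 Uvalde 2019 replicate 3, and 5439 with sample weights. MELO3C031322.2 also missed the threshold without F39 Arizona replicate 1 or 2 or TTDV Arizona replicate 1, 2 or 3 (adjusted p up to 0.104), and MELO3C024582.2 without F39 Arizona replicate 1 or TTDV Arizona replicate 2 or 3 (adjusted p up to 0.059).

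At California, MELO3C005246.2 had 397 ± 253 reads (SD, n = 6) against 0.74 ± 2.16 at the other 4 shared locations of 2019 (n = 23, of which 17 had no read), a difference of 4.25 ± 0.17 (SE, limma adjusted p = 1.93e-17). MELO3C020157.2 was higher by 2.70 ± 0.43 (adjusted p = 0.000914), at 1429 ± 403 against 209 ± 113 reads, and MELO3C007140.2 differed by -1.36 ± 0.24 (adjusted p = 0.00288). MELO3C015743.2 differed by -1.35 ± 0.33 (adjusted p = 0.0492) and missed the threshold without each of 24 of the 29 libraries in turn (adjusted p from 0.00826 to 0.188) and under 5 of 10 other alternatives (0.000318 to 0.118). In all 99 genes passed, 70 higher and 29 lower. The count was 23, 60 and 30 without F39 California replicates 1, 2 and 3, 36, 29 and 25 without TTDV California replicates 1, 2 and 3, 61 without TTDV Georgia replicate 1, and 163 without TTDV Uvalde 2019 replicate 2. It was 192 without the Uvalde 2019 libraries, 229 without F39 Georgia replicates 2 and 3, 333 without TTDV North Carolina replicate 3 and F39 Uvalde 2019 replicate 3 and 2580 with sample weights.

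The TTDV fruits of Indiana, compared with TTDV of the other 5 locations of 2019, differed in 3 genes, 2 of which are named after their values were seen. Chance could not be excluded for this count, as 11 of 100 splits of the samples gave at least 3 genes (highest 2173). MELO3C024235.2 was higher by 2.10 ± 0.35 (SE, limma adjusted p = 0.0128), at 124 ± 56.7 reads (SD, n = 3) against 11.8 ± 11.4 (n = 14). MELO3C014427.2 was higher by 2.30 ± 0.39 (adjusted p = 0.0128) and MELO3C018417.2 differed by -1.76 ± 0.21 (adjusted p = 7.76e-05). MELO3C014427.2 missed the threshold without Indiana replicate 1 (difference 1.46, adjusted p = 0.288) and in the fit over the compared groups only (adjusted p = 0.0875, against 0.00222 to 0.0875 over the alternatives). At unadjusted p under 0.05 there were 1350 genes, and voom gave 5 past the threshold, the fit over the compared groups 12, the fit without TTDV North Carolina replicate 3 and F39 Uvalde 2019 replicate 3 16 and sample weights 798. The count was 11 and 7 without Indiana replicates 1 and 2, and MELO3C024235.2 missed the threshold without replicate 3 (adjusted p = 0.303, against 0.00743 to 0.303 over the libraries left out in turn). Without the Uvalde 2019 libraries, limma gave 0 genes, with 1386 at unadjusted p under 0.05, and MELO3C018417.2 differed by -0.77 (adjusted p = 0.275).

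Between the years at Uvalde, MELO3C025025.2 had 364524 ± 370643 reads in 2018, above its mean at Arizona, against 5691 ± 2857 in 2019 (SD, n = 6 each), a difference of 5.22 ± 0.65 (SE, limma adjusted p = 6.81e-06). MELO3C009872.2 was higher in 2018 by 4.35 ± 0.47 (adjusted p = 9.03e-07). MELO3C004373.2 differed by -7.91 ± 1.24 (adjusted p = 0.000103), at 29.5 ± 18.4 against 207295 ± 329924 reads, and MELO3C022883.2 by -7.37 ± 0.82 (adjusted p = 1.05e-06), with no read in 5 of the 6 libraries of 2018 and 9575 ± 8847 reads in 2019. In all 3722 genes passed the threshold, 1993 higher and 1729 lower in 2018 (53.5% higher, and 49.5% after quantile normalization). A fit over these groups alone gave 1441 and sample weights 5637.

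**Figure D4:**
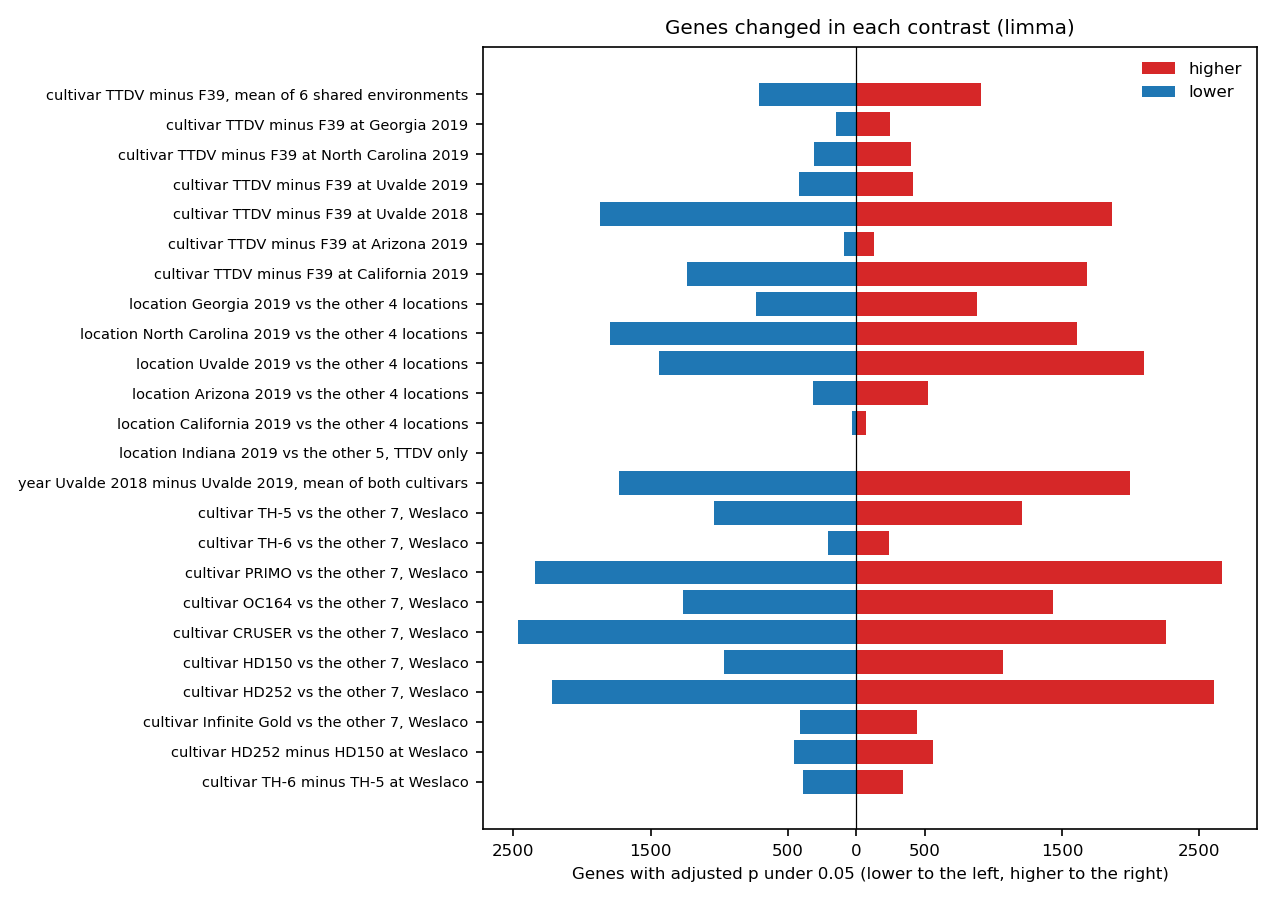
Bars give the number of genes past the limma threshold in each comparison, higher to the right and lower to the left of 0. Counts run from 3 for Indiana to 5009 for PRIMO at Weslaco.

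Among the 8 cultivars grown at Weslaco, 9934 of 17131 genes differed. PRIMO differed from the mean of the other 7 in 5009 genes (2665 higher and 2344 lower), HD252 in 4828 (2610 and 2218), CRUSER in 4724 (2258 and 2466), OC164 in 2701 (1435 and 1266), TH-5 in 2242 (1205 and 1037), HD150 in 2033 (1067 and 966), Infinite Gold in 853 (445 and 408) and TH-6 in 442 (236 and 206). With voom the higher share moved from 47.8% to 68.7% in CRUSER, from 53.4% to 76.5% in TH-6, from 52.2% to 68.1% in Infinite Gold, from 53.1% to 67.7% in OC164, from 52.5% to 65.5% in HD150 and from 53.7% to 64.4% in TH-5, so the balance of directions in these cultivars depends on the method.

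In CRUSER, MELO3C011170.2 had 12930 ± 10245 reads (SD, n = 3) against 40.3 ± 58.5 in the others (n = 21), a difference of 7.61 ± 0.55 (SE, limma adjusted p = 4.61e-08), and MELO3C034973.2 had no read in the 3 libraries against 152 ± 65.3 in the others (adjusted p = 3.06e-08). In HD252, MELO3C018664.2 had 3692 ± 2630 reads against 77.8 ± 184 (difference 6.28 ± 0.48, adjusted p = 3.13e-08), while MELO3C015419.2, higher at Uvalde 2019, had 187 ± 102 against 44192 ± 47222 (difference -7.08 ± 0.82, adjusted p = 1.15e-05). In PRIMO, MELO3C009383.2 had 5117 ± 2209 reads against 94 ± 141 (difference 6.07 ± 0.67, adjusted p = 7.22e-06), and MELO3C013159.2 had 22.7 ± 13.6 against 2648 ± 4387 (difference -4.88 ± 0.58, adjusted p = 1.57e-05). In OC164, MELO3C021851.2 had 1515 ± 612 reads against 151 ± 149 (difference 3.48 ± 0.29, adjusted p = 1.11e-07), and MELO3C015076.2 had 369 ± 195 against 4238 ± 2649 (difference -3.17 ± 0.32, adjusted p = 2.13e-06).

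MELO3C024829.2 was highest in TH-5 and lowest in HD150. It had 3078 ± 1717 reads in TH-5 against 209 ± 340 in the others (SD, n = 3 and 21, difference 4.72 ± 0.63 (SE), limma adjusted p = 0.000124). In HD150 it had 1.42 ± 1.29 against 649 ± 1198 (difference -3.22 ± 0.63, adjusted p = 0.00266), which voom did not call (adjusted p = 0.11, against 0.000406 to 0.11 over the alternatives). MELO3C015852.2 was higher in HD150, at 915 ± 369 against 43.3 ± 90.9 reads (difference 4.47 ± 0.36, adjusted p = 8.34e-08). TH-6 had 229 ± 106 reads of MELO3C033088.2 against 5.76 ± 17.1 (difference 3.47 ± 0.32, adjusted p = 8.26e-07) and 0.27 ± 0.46 of MELO3C026792.2 against 213 ± 163 (difference -3.41 ± 0.26, adjusted p = 1.52e-07). Infinite Gold had 772 ± 648 reads of MELO3C005088.2 against 48.4 ± 59.5 (difference 3.45 ± 0.44, adjusted p = 6.87e-05) and 3.11 ± 2.68 of MELO3C021842.2 against 238 ± 193 (difference -2.90 ± 0.43, adjusted p = 0.000365).

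Single libraries moved the Weslaco counts. The TH-5 count was 856 and 549 without TH-5 replicates 2 and 3, the TH-6 count 259, 127 and 231 without TH-6 replicates 1, 2 and 3, and the PRIMO count 2340 and 2740 without PRIMO replicates 1 and 2. Without replicate 1 the OC164 count was 1303 and the CRUSER count 2414. The HD150 count was 932, 860 and 1020 without HD150 replicates 1, 2 and 3, the HD252 count 2820 and 2425 without HD252 replicates 1 and 2, and the Infinite Gold count 308, 237 and 346 without its replicates 1, 2 and 3. With voom the CRUSER count was 2747. Sample weights gave 5854 for TH-5, 786 for TH-6, 8010 for PRIMO, 1305 for OC164, 1771 for CRUSER, 4001 for HD150, 8208 for HD252 and 2187 for Infinite Gold.

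Between HD252 and HD150, MELO3C002943.2 had 7.35 ± 2.13 reads in HD252 and 17717 ± 3415 in HD150 (SD, n = 3 each), a difference of -9.02 ± 0.43 (SE, limma adjusted p = 8.04e-11), and MELO3C016815.2 differed by -7.80 ± 1.30 (adjusted p = 0.0016). MELO3C016167.2, which was lower in TTDV than in F39 outside Uvalde 2019, had 7264 ± 1694 reads in HD252 and 108 ± 65 in HD150 (difference 5.81 ± 0.50, adjusted p = 4.1e-07). In all 1013 genes passed, 558 higher and 455 lower in HD252. The count was 528 and 511 without HD150 replicates 1 and 3, and 517 and 336 without HD252 replicates 1 and 2. Sample weights gave 3932.

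Between TH-6 and TH-5, MELO3C015130.2 had 4543 ± 2305 reads in TH-6 and 37.1 ± 1.31 in TH-5 (SD, n = 3 each), a difference of 5.94 ± 0.34 (SE, limma adjusted p = 6.22e-10). MELO3C027408.2 had 1257 ± 584 against 0.23 ± 0.39 reads (difference 5.97 ± 0.40, adjusted p = 6.03e-09). MELO3C005215.2 had no read in TH-6 and 450 ± 362 in TH-5 (adjusted p = 0.00327, and 0.0715 with voom, against 0.00048 to 0.0715 over the alternatives). In all 732 genes passed, 342 higher and 390 lower in TH-6. The count was 253 and 140 without TH-5 replicates 2 and 3, and 167 and 377 without TH-6 replicates 2 and 3. Sample weights gave 2682.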

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

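The tests of the Uvalde 2019 labels, of mixed RNA in the F39 Georgia libraries, of equal size factors and the counts without Uvalde 2019 were chosen after the result was seen. The effect of a location differed between F39 and TTDV, by a test of the difference itself, in 2675 genes at Uvalde 2019, 1117 at California, 306 at North Carolina and 88 at Arizona, and the effect of the year at Uvalde differed in 2499. At Georgia limma found 0 genes, with 1721 at unadjusted p under 0.05. These counts use the Uvalde 2019 libraries as labelled, and an exchange of labels there would by itself enter the counts of Uvalde 2019 and the year and the baseline of the others. Without these libraries the counts were 696 at California, 421 at Arizona, 71 at North Carolina and 0 at Georgia (limma, 1618 at unadjusted p under 0.05). The California effect on MELO3C005246.2 was smaller in TTDV (difference -1.27, SE 0.33, adjusted p = 0.0233, and -1.29, SE 0.32, adjusted p = 0.0269 without Uvalde 2019), at 221 ± 103 reads against 573 ± 239 in F39 (SD, n = 3 each).

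The cultivar difference at Uvalde 2019 ran against the other environments. An exchange of the cultivar labels there is a candidate explanation, since 6 of 6 libraries lay on the other cultivar's side, which an exchange needs in both groups. A response of both cultivars to the field would have left part of the marker genes in their usual order, but 100% of the 43 markers were exchanged in both groups. Scaling is argued against, as 88.7% of the cultivar genes had the opposite sign after quantile normalization (595 of 671, against 589 before it). Where along the work an exchange arose, in the field, the laboratory or the labels, stays open.

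TTDV North Carolina replicate 3 and F39 Uvalde 2019 replicate 3 correlated with each other at r = 0.976 across genes, against 0.853 to 0.891 with their own groups. They were not 1 library under 2 labels, as their median squared difference per gene was 11.1 times the Poisson value. Abundant genes and depth are argued against, as the pair still correlated at 0.969 without the 1000 most abundant genes (own groups up to 0.864) at 0.972 after thinning to equal total reads (up to 0.887) and at 0.975 after thinning to equal size factors (up to 0.889). Their recovered reads per unit of size factor, 24158246 and 22711143, lay above the 11932645 to 19699843 of the other libraries of the table. The pair differed no more than libraries of 1 group do, for which the median of the table was 20.83 times the Poisson value (lowest 5.49) and r = 0.967. By the marker genes both lay at the TTDV level (median scores 0.944 and 1.12), as did the other libraries labelled F39 at Uvalde 2019. Whether the labels place these 2 libraries in their right groups was not tested. A stage or condition of these fruits that the labels do not give stays open and was not tested.

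F39 Georgia replicates 2 and 3 had 34.9% of the 43 marker genes on the TTDV side. TTDV RNA mixed into them would raise each TTDV-high gene by about the same share, yet at least 40.9% of those expected to have 20 reads or more lay below 20% of the mixture's level. Plants of mixed genotype might leave neighbouring markers in the same state. Neighbours were taken as successive markers in the order of the table, without coordinates, so they may lie far apart in the genome. In a wider set of 95 markers the frequency of neighbours in the same state was set against 100000 shuffles. The one-sided permutation p was 0.076 in replicate 2 and 0.0217 in replicate 3. By the criterion set beforehand, a higher p of at least 0.05, this explanation would be ruled out, but that criterion was wrong, since a p that misses the threshold does not show an absence of clustering and replicate 3 was below it, and the explanation was left open after the p-values were seen.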

How the results depend on the processing

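The tests with voom, without the Uvalde 2019 libraries, without the pair of resembling libraries, without both F39 Georgia libraries and the gene-by-gene sample weights were chosen after the data were seen. Of 69 gene results named by the rule, 0 changed direction in the alternatives run. Among the 6 further named genes (4 from the comparison without Uvalde 2019 and 2 at Indiana), 0 of 208 values changed direction and 4 missed the threshold, all at Indiana. All these named genes were chosen as past the threshold in the same libraries, most with a condition on direction or overlap. A change of direction was therefore unlikely from the start, and its absence says little. No paired analysis was possible because the columns and labels carry no replicate numbers. Moderation without trend and robust settings, quantile normalization and no filter each left the 28 counts within 1.5 times. Simulated 2-fold and 4-fold changes, set only in genes with more reads than the filter asks for, were recovered in 24% and 58% of cases for the cultivars at Arizona, 48% and 90% for the California location and 16% and 68% for Indiana. Unless stated otherwise the cause was not tested. Gene-by-gene sample weights raised most counts, and lowered those of OC164 (1305) and CRUSER (1771). The environment counts became 12261 (F39) and 12830 (TTDV), the mean cultivar difference 4536 and the interaction 11677. The cultivar difference became 811 at Georgia, 4069 at North Carolina, 1655 at Uvalde 2019, 5684 at Uvalde 2018, 3773 at Arizona and 8209 at California. The locations became 2651 (Georgia), 7806 (North Carolina), 6498 (Uvalde), 5439 (Arizona), 2580 (California) and 798 (Indiana), and the year 5637. At Weslaco the counts became 5854 (TH-5), 786 (TH-6), 8010 (PRIMO), 4001 (HD150), 8208 (HD252), 2187 (Infinite Gold), 3932 (HD252 against HD150) and 2682 (TH-6 against TH-5). The default weights, which did not converge on the first table, differed from these by over 1.5 times in 6 counts. They gave 505 for the cultivar difference at North Carolina and 3396 at Uvalde 2019, 3835 for the North Carolina and 4081 for the California location, 1367 for TH-6 and 4056 for TH-6 against TH-5.

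The fit over the compared groups only gave 7 genes at Georgia, 93 at North Carolina, 49 at Uvalde 2019, 703 at Arizona and 4444 at California for the cultivar difference, 12 for Indiana and 1441 for the year. The stricter filter, with fewer genes tested, gave 145 for the cultivars at Arizona. Voom gave 434 for the cultivars at Uvalde 2019, 5 for Indiana and 2747 for CRUSER. Without the Uvalde 2019 libraries the mean cultivar count was 3642, that at North Carolina 1162, and the location counts 678 (Georgia), 1445 (Arizona), 192 (California) and 0 (Indiana, limma, with 1386 at unadjusted p under 0.05). Without the resembling pair the mean cultivar count was 2454 and the locations 2586 (Georgia), 1518 (Arizona), 333 (California) and 16 (Indiana). Without F39 Georgia replicates 2 and 3 the locations were 735 (Georgia) and 229 (California).

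Leaving out each library in turn gave, for the cultivar difference, 38 to 456 at Georgia, 219 to 1499 at North Carolina, 2466 to 3402 at Uvalde 2018, 92 to 206 at Arizona and 1634 to 2984 at California. The locations ranged over 25 to 1935 (Georgia), 295 to 1090 (Arizona), 23 to 163 (California) and 3 to 11 (Indiana). At Weslaco the ranges were 549 to 2586 (TH-5), 127 to 578 (TH-6), 2340 to 5513 (PRIMO), 1303 to 3308 (OC164), 2414 to 5202 (CRUSER), 860 to 2335 (HD150), 2425 to 5198 (HD252), 237 to 979 (Infinite Gold), 336 to 936 (HD252 against HD150) and 140 to 843 (TH-6 against TH-5). Of 69 named gene results, 12 missed the threshold in at least 1 such fit, and 6 missed it with voom.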

Other observations

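The tests on the Texas fields were chosen after the result was seen, while those on neighbouring genes, main axes and other splits were written before. The 664 genes higher at Uvalde 2019 were also read at Weslaco, with a median over libraries of 46.7 reads against 163 at Uvalde 2019, 21.6 at Uvalde 2018 and 5.93 to 9.5 at the 5 fields outside Texas. The genes were chosen as higher at Uvalde 2019 than at Georgia, North Carolina, Arizona and California, so low reads at these fields follow from the choice. Indiana, which the choice did not use, had 7.11 to 10.03 reads. The sources do not say whether Weslaco was normalised with the other libraries, but the shared lowest value of 4.182278 points to 1 transformation of both tables. F39 Uvalde 2019 replicate 3 had 31.2, below the highest library from outside Texas (35.2). The 664 genes took 0.88% to 26.2% of the reads of a Weslaco library. A count against the libraries from outside Texas cannot show a feature shared by the Texas fields, since the genes were chosen as lower at most of the outside fields. In that count, 16 of 24 libraries at Weslaco and only 2 of 6 at Uvalde 2018 lay above the highest library from outside Texas, a North Carolina library (60.0% together). The lowest, at 6.7 reads in HD252 replicate 1 and 9.58 at Uvalde 2018, lay within the range of 3.16 to 35.2 outside Texas, and the fields differ in cultivar and year, so the explanation stays open.

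The first principal components of both tables had related gene loadings, with r = 0.636 (rho = 0.591) across 16584 genes, which are not independent replicates. The hypothesis that the main axis among the Weslaco cultivars recurs among the environments passed its criterion (r above 0.5 in size), and what the axis represents was not tested. Over the 6 shared environments, the variance between group means divided into 50.9% for environment, 9.6% for cultivar and 39.5% for their interaction, and without Uvalde 2019 into 43.6%, 19.3% and 37.1%. These shares hold sampling noise. The mean variance of libraries within groups was 0.28, and that between groups was 0.32. A mean over the libraries of a group varies less than a single library, so these values do not give the part that is noise. They are also not adjusted for the number of levels, which is larger for environment than for cultivar. Noise alone would therefore give environment the larger share, and the shares do not rank the factors.

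Neighbouring genes in the order of the table were tested for changing together. Among the 500 genes of smallest p, the cultivar difference outside Uvalde 2019 had 3.58 times the neighbouring pairs expected by chance. The hypothesis that cultivar differences cluster more than location differences was not borne out, since the Uvalde 2019 location had 5.99 times, although the other 4 locations had 0.7 to 1.25 times. HD252 against HD150 had 2.13 times and TH-6 against TH-5 1.79 times.

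Other splits of the samples were run for each count of the report's main tests except the cultivar difference at Georgia, where TTDV had 2 libraries. The 100 splits shuffled the labels of all groups at once, so real differences of other groups entered the spread. The splits treat each library as independent, and the labels do not say whether libraries of a group came from separate plants or fields. If they did not, the splits cannot tell an environment or cultivar from a plant or plot. Taking the libraries as independent, the splits exclude chance for the environments, for F39 against TTDV and for the 8 Weslaco cultivars only as a whole. For 1 location, 1 Weslaco cultivar, the year or the interaction alone they cannot. With a share under the 0.05 set beforehand, 1 of 100 splits (the real one) was as large for the environment effect in F39 (6567 genes, highest other 639) and TTDV (5519, 230), the mean cultivar difference (1621, 604), the interaction (5102, 2618), the locations Georgia (1611, 798), North Carolina (3408, 243), Uvalde (3536, 1035) and California (99, 39), the year (3722, 2421), the 8 cultivars together (9934, 153) and TH-5 (2242, 192), PRIMO (5009, 72), OC164 (2701, 574), CRUSER (4724, 2222), HD150 (2033, 457), HD252 (4828, 78) and Infinite Gold (853, 302). For Arizona (838, 1422) and TH-6 (442, 1028), 2 of 100 splits were as large, which is also a share under 0.05. In both, however, another split gave more genes than the real one. For Indiana, 11 of 100 splits gave at least its 3 genes, and the highest gave 2173, so chance could not be excluded there, and splits with many times the real count point to a structure among the TTDV libraries. The 10 splits of 3 libraries against 3 are too few for a share under 0.05. They gave 707 genes for the cultivars at North Carolina (highest other 13), 830 at Uvalde 2019 (203), 3729 at Uvalde 2018 (89), 222 at Arizona (0), 2920 at California (0), 1013 for HD252 against HD150 (1) and 732 for TH-6 against TH-5 (3).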
